A study of Mus musculus with 2 samples.

How the data were processed

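Gene expression was measured by RNA sequencing of total RNA from 2 subcutaneous mouse tumours, 1 library from a Kras line with Brg1 deletion and 1 from a Kras line with heterozygous p53 loss, grouped by the genotype in the labels. The deposited values are RPKM per gene, the unit the authors gave in the names of the tables, which have no header line and give a gene name and a value in each row. The submitters' processing notes name CASAVA 1.7, TopHat 1.3.1, SAMtools 0.1.13 and the mouse build mm9, with no role or order. The gene annotation, the use of strand and the treatment of reads that map to several places are not given in the sources used here. Without strand, reads of overlapping antisense genes cannot be separated, and a gene with a near-identical copy can gain or lose reads to it.

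The tables hold no counts, so the depth is unknown and no counting interval or floor was computed. The RPKM values summed to 199548 in the Brg1-deleted tumour and 203840 in the p53 heterozygous tumour, and the 20 most abundant genes held 6.53% and 5.78% of these sums. To look for the value of 1 read, the ratios of 467 genes below 0.3 RPKM in both libraries were placed in bins of 0.05 on the log2 scale. The fullest bin held 2.78% of them, so no step was seen and the relative depth was not recovered. In the Brg1-deleted tumour 14130 genes were listed at 0 and in the p53 heterozygous tumour 13119, among them 353 and 191 measured genes.

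Because each group had 1 library, the difference between the tumours has no replicate check, and no p-value or standard deviation across genes is given for it. A standard error over genes served only to set the bound of the scaling test of chromosome medians. The log2 ratio of a gene was log2 of (RPKM + 1) in the Brg1-deleted tumour minus that in the p53 heterozygous tumour, for genes with at least 1 RPKM in at least one library. This pseudocount of 1 understates the ratio of low genes, so folds in the text are ratios of the deposited RPKM values, and genes at 0 have none. A fold that rests on a value well below 1 RPKM is imprecise. Genes at or past a log2 ratio of 2 or −2 were counted as at least 4-fold higher or lower, and list members at or past 1 or −1 as at least 2-fold higher or lower. These counts are on the log2(RPKM + 1) scale, so a low gene can pass 2-fold in its deposited values and not be counted. Intervals given for differences between gene groups come from 10000 bootstrap draws over genes, and 1 comparison of gene groups was placed among 100000 random reassignments. They describe genes of these libraries and say nothing of the spread between tumours.

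The 48 gene lists, the groups, the rule for naming genes and the first set of alternatives were fixed before the data were examined. Of the 993 list entries 974 were found among the row names. A list with at least 4 measured members was described by its median log2 ratio and the percentile of that median among 10000 random lists of the same size, drawn from measured genes in the same 20 bins of mean expression. A list was called higher at a percentile of at least 97.5 and lower at one of at most 2.5. The named genes are those of the genotypes with Smarca2, Ptf1a and Cdkn2a, the 12 genes with the largest and the 12 with the smallest log2 ratio among genes of at least 10 RPKM in the higher library, leaving out clone and locus names, and in each list the 3 members with the largest absolute ratio and the member with the highest mean. For some lists fewer are printed. Genes named outside this rule, such as Kpna2, Mtap and Uty, were chosen after their values were seen or complete a list.

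Row names were matched to RefSeq genes of GRCm38.p6, where 19357 were current symbols and 2944 were older names of 1 gene. GRCm38 is not the build of the files, so it was used for names, chromosomes, neighbours and transcript sequences, and no coordinate is printed. For near-identical copies, the longest coding transcript of each gene in GENCODE M21 was aligned to all other transcripts with minimap2 2.31, and a match of at least 95% identity over at least 200 bases and 30% of the transcript counted as a copy. This search covered 12373 measured genes, of which 799 had a copy.

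The procedures were tested on simulated libraries of 12969 genes with noise of 0.2 (SD, log2). Changes were planted only in genes with a mean of at least 10 RPKM, and noise was drawn for each gene alone. The 4-fold rule took 99 of 100 genes changed 8-fold, 5 of 100 genes changed 3-fold and 0 of 12769 unchanged genes. The list procedure called 20 of 20 lists with a planted 2-fold shift and 2 of 41 lists without one. The real spread between libraries of one genotype is unknown and can be larger. Between the 2 real libraries the median absolute log2 ratio of genes without a near-identical copy was 0.47. Recovery of lower genes and lists whose members vary together were not simulated, so these rates need not hold for the real libraries. Alternatives were pseudocounts of 0.1 and 5 RPKM, centring on the median of the genes with at least 1 RPKM in both libraries, rescaling to equal sums, no filter and a minimum of 5 RPKM, a log2 threshold of 1 and random lists not matched on expression. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.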

Results

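RNA sequencing was available for 2 mouse pancreatic ductal adenocarcinomas grown under the skin from cancer cell lines, with 1 library for each genotype. The first tumour came from a line in which Cre recombinase, driven from the Ptf1a locus of pancreatic progenitor cells, accompanied a Kras allele and deletion of Brg1, the ATPase of the SWI/SNF chromatin remodelling complex that is encoded by Smarca4. The second came from a line labelled with Ptf1a, written without Cre, a Kras allele and heterozygous loss of p53, encoded by Trp53. The comparison asks how the transcriptome of the Brg1-deleted tumour differs from that of the p53 heterozygous tumour. Each library listed 29863 genes in RPKM (reads per kilobase of transcript, scaled to the mapped reads of the library), of which 12280 in the Brg1-deleted tumour and 12761 in the p53 heterozygous tumour reached 1 RPKM. A gene was taken as measured when it reached 1 RPKM in at least one library, which held for 13654 genes. Across these genes, which are not independent replicates, Spearman's rho between the libraries was 0.83. There were no replicates and the read depth is unknown, so no difference between the tumours has a replicate error or a test. Higher and lower refer to the Brg1-deleted tumour relative to the p53 heterozygous tumour, and the fold given for a single gene is the ratio of its RPKM values as deposited. The genotypes differ at both Brg1 and p53, the tumours came from different lines, and they differed in Xist and Y-linked RNA as given below. A difference therefore cannot be assigned to either gene.

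Smarca4 and Trp53, the genes reduced in the genotypes, differed in the direction of the labels. Smarca4 was 6.03-fold lower in the Brg1-deleted tumour, at 4.45 RPKM against 26.9 RPKM (log2 ratio −2.35). Trp53 was 9.45-fold higher, at 26.5 RPKM against 2.80 RPKM in the p53 heterozygous tumour (log2 ratio 2.85), and a separate row named p53 held 45.3 and 4.14 RPKM. This difference is larger than the loss of a single copy alone would give if the other copy were as active as in the Brg1-deleted tumour, while the neighbouring genes Wrap53, at 4.05 and 4.01 RPKM, and Atp1b2, at 1.38 and 1.44 RPKM, both chosen after the values of Trp53 were seen, hardly differed. Smarca2, which encodes Brm, the alternative ATPase of the SWI/SNF complex, was 2.92-fold higher at 12.4 against 4.24 RPKM. Kras stood at 13.8 and 21.6 RPKM, a 1.57-fold difference, and Ptf1a, a transcription factor of pancreatic progenitors and acinar cells, was listed at 0 in both libraries. These values cover the whole gene, including exons outside a deletion, and the RNA of host cells in the tumour, so they are a limited check of the labels. With a pseudocount of 5 RPKM the log2 ratio of Smarca4 was −1.75, short of the 4-fold rule.

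Cdkn2a, which encodes the p16Ink4a and p19Arf tumour suppressors, was listed at 0 in the Brg1-deleted tumour and at 44.7 RPKM in the p53 heterozygous tumour. Its neighbours on chromosome 4, chosen after this value was seen, went in opposite directions. The related inhibitor gene Cdkn2b was 6.05-fold lower, at 3.04 against 18.4 RPKM. Mtap, which encodes an enzyme of methionine salvage, was 3.98-fold higher, at 108 against 27.0 RPKM. Some genes that every cell uses, such as the respiratory chain gene Ndufs5 and the nuclear import gene Kpna2 (the latter named after its values were seen), were also listed at 0 in one library. Both of these have a near-identical copy with which they can share reads, whereas the search found none for Cdkn2a. What lies behind its value was not tested, and a value of 0 is given only as listed and without a fold.

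**Figure D1:**
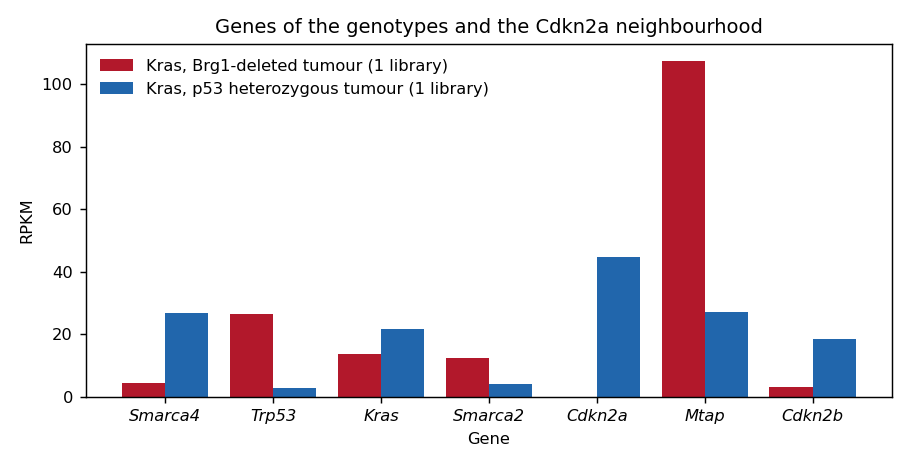
RPKM of 7 genes in the Brg1-deleted tumour (red bars) and the p53 heterozygous tumour (blue bars), 1 library each and without error bars. Smarca4 stands at 4.45 and 26.9 RPKM, Trp53 at 26.5 and 2.80 RPKM, and Cdkn2a is listed at 0 in the Brg1-deleted tumour.

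Of the 13654 measured genes, 159 were at least 4-fold higher and 340 at least 4-fold lower in the Brg1-deleted tumour on the log2(RPKM + 1) scale, together 3.65% of the genes. These counts depend on the pseudocount and were 561 and 981 with a pseudocount of 0.1 RPKM, 37 and 59 with one of 5 RPKM and 523 and 873 after rescaling to equal sums. Among the 12 genes with the largest ratios, Tff3, a trefoil factor of goblet cells, was 111-fold higher at 134 against 1.20 RPKM. Pga5, the precursor of the gastric protease pepsin, was at 37.9 against 0.214 RPKM, and Isx, an intestinal homeobox gene, at 15.5 against 0.146 RPKM. The alcohol dehydrogenase gene Adh1 was 21.3-fold higher at 42.2 RPKM, Fxyd6, a regulator of the sodium pump, 35.2-fold higher at 44.0 RPKM, and Ms4a8a 48.8-fold higher at 31.8 RPKM. Cxcl11, an interferon-induced chemokine, was at 16.6 against 0.121 RPKM. Hoxa10, the small nucleolar RNA gene Snord49b and Ndufs5 were at 11.3, 11.5 and 13.2 RPKM and were listed at 0 in the p53 heterozygous tumour. The ribosomal protein gene Rpl30 was at 88.3 against 3.62 RPKM and the pseudogene Rpl34-ps1 at 29.5 against 0.607 RPKM. Rpl30, Rpl34-ps1 and Ndufs5 have near-identical copies elsewhere in the genome with which they can share reads, so their values are uncertain, as are those of Kpna2, Uhrf1, Lyz2, H2-T23 and Ndufs3, which also have such copies. With a pseudocount of 5 RPKM, Hoxa10, Snord49b, Ndufs5 and Isx no longer passed the 4-fold rule, with log2 ratios from 1.71 for Hoxa10 to just under 2 for Isx.

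The 12 genes with the smallest ratios were far lower in the Brg1-deleted tumour. Wfdc2, a secreted protein with the fold of protease inhibitors, was 145-fold lower at 2.12 against 308 RPKM. Lcn2, an iron-sequestering lipocalin made by neutrophils and epithelia, was 41.2-fold lower at 5.63 against 232 RPKM. Gabrp, a subunit of the GABA type A receptor, was at 0.384 against 95.5 RPKM, and Nrn1, which encodes neuritin, at 0.278 against 79.8 RPKM. Tm4sf4, Scara3 and the cornified envelope gene Ivl were 88.2-fold, 63.1-fold and 28.5-fold lower, from 102, 107 and 109 RPKM in the p53 heterozygous tumour. The matrix metalloproteinase gene Mmp7 and the embryonic claudin gene Cldn6 were listed at 0 in the Brg1-deleted tumour and at 62.7 and 37.4 RPKM in the other. Hmga2, a chromatin protein of embryonic tissue, was at 0.004 against 25.4 RPKM. Ldhb, a lactate dehydrogenase gene with a near-identical copy, was listed at 0 against 29.4 RPKM and is uncertain for that reason. The median log2 ratio was −0.13 over all measured genes and −0.10 over the 11387 genes with at least 1 RPKM in both libraries, on which ratios were centred as an alternative.

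**Figure D2:**
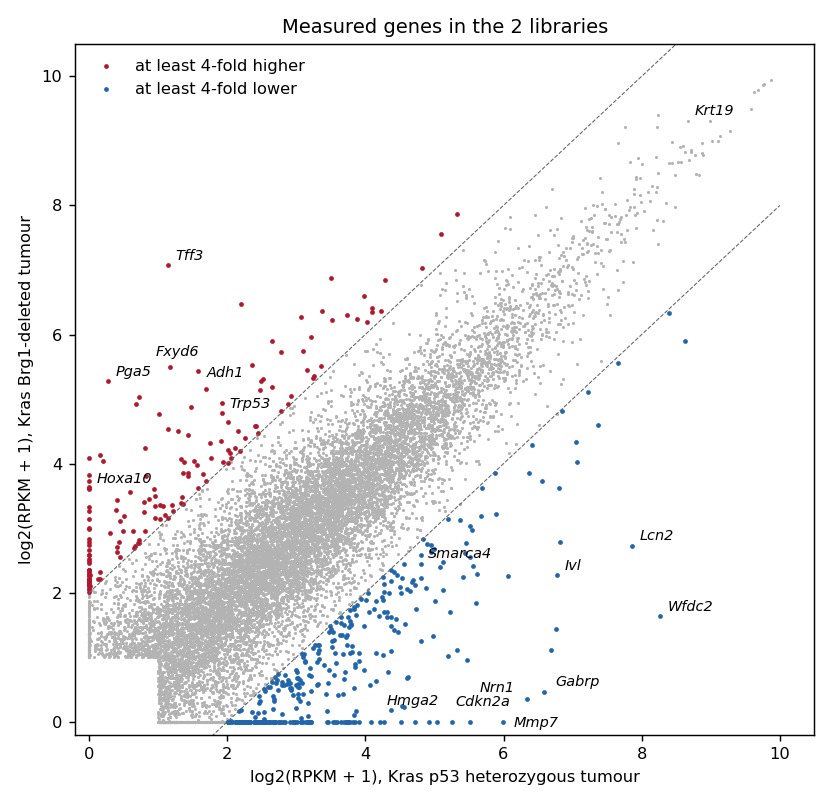
log2(RPKM + 1) of the 13654 measured genes in the p53 heterozygous tumour (horizontal axis) and the Brg1-deleted tumour (vertical axis), 1 point per gene. Red points are the 159 genes at least 4-fold higher and blue points the 340 genes at least 4-fold lower in the Brg1-deleted tumour, and the dashed lines mark 4-fold.

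Of 48 gene lists, 46 had at least 4 measured members, and 13 of these lay higher and 8 lower than the central 95% of random lists of the same size and expression. By chance 2.3 lists are expected, but only if the members of a list vary independently. Genes of one list can vary together and some lists share members, so these counts do not show an excess over chance. The percentiles given below describe these libraries and are not a test. Counts of members at least 2-fold higher or lower are on the log2(RPKM + 1) scale, on which members with low values can fall short although their deposited values differ by more. Markers of gastric and intestinal mucosa were higher, with a median log2 ratio of 0.84 (percentile 100), 8 of 21 members at least 2-fold higher and 3 at least 2-fold lower. The membrane mucin gene Muc13 was 7.95-fold higher at 24.1 against 3.03 RPKM, and the abundant mucosal gene Dmbt1 stood at 507 and 347 RPKM, while Muc6, the mucin of gastric glands, was 18.4-fold lower at 2.58 against 47.6 RPKM. Classical subtype genes of pancreatic carcinoma, several of which are also on the mucosal list, had a median of 0.74 (percentile 100), with 5 of 17 members at least 2-fold higher and 0 lower. Agr2, a disulfide isomerase of mucus-secreting cells, was 6.45-fold higher at 95.4 RPKM, the trefoil factor gene Tff2 3.32-fold higher at 224 RPKM, and Lgals4, a galectin of the gut epithelium, was at 426 against 246 RPKM. Basal-like subtype genes had a median of 0.56, at percentile 96.2 and so within the central range, with 2 of 8 members at least 2-fold higher and 2 lower, Tns4 8.87-fold lower at 3.21 RPKM and Ly6d at 76.0 and 51.3 RPKM. This list lay higher with a pseudocount of 5 RPKM, at percentile 98.3, and against random lists not matched on expression, at percentile 98.8.

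Ductal cell markers moved apart, with 3 of 17 members at least 2-fold higher and 3 at least 2-fold lower and a median of −0.09 (percentile 33.6). Prom1, a surface protein of duct cells, was 5.89-fold higher at 232 RPKM, whereas the keratin gene Krt7 was 6.77-fold lower at 58.5 against 396 RPKM. The secreted phosphoprotein gene Spp1 was at 718 and 763 RPKM. General epithelial genes had a median of −0.28 (percentile 6.56) with 1 of 29 members at least 2-fold higher, the tight junction gene Ocln at 15.9 against 6.85 RPKM, and 7 at least 2-fold lower, among them Cdh3, which encodes P-cadherin, 5.74-fold lower at 1.79 RPKM, and the claudin gene Cldn4, 4.08-fold lower at 3.12 RPKM. Krt19 was the most abundant member, at 635 and 405 RPKM. Squamous cornification genes had a median of −0.14 (percentile 47.6), with Sprr1a at 570 and 622 RPKM. Endocrine cell markers lay in the higher range, with a median of 1.96 (percentile 100), but this rests on 4 measured members that were all listed at 0 in the p53 heterozygous tumour. In the Brg1-deleted tumour the granin genes Chgb and Chga were at 7.83 and 1.37 RPKM, the synaptic vesicle gene Syp at 3.39 RPKM and the transcription factor gene Neurod1 at 2.45 RPKM. Without genes listed at 0 too few members remain to place this list. Acinar cell markers had a median of 0.89 (percentile 98.4) from 4 measured members, with Gata4, a transcription factor of foregut tissues, 3.91-fold higher at 26.4 RPKM and the elastase gene Cela1 at 5.76 and 4.07 RPKM. Without the filter on low values the medians of the acinar and endocrine lists were 0, and the acinar list also returned to the central range with pseudocounts of 0.1 and 5 RPKM, at percentiles 95.9 and 96.8, and after rescaling to equal sums, at percentile 95.6.

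Genes of the interferon response and of antigen presentation were higher in the Brg1-deleted tumour. Interferon response genes had a median log2 ratio of 0.83 (percentile 100), with 12 of 26 members at least 2-fold higher and 0 at least 2-fold lower. Oasl2 and Oas2, of the oligoadenylate synthetase family of antiviral proteins, were 4.81-fold and 6.55-fold higher at 44.5 and 8.63 RPKM, and the chemokine gene Cxcl10 was at 9.79 against 0.328 RPKM. The MHC class I presentation genes, which display peptides to cytotoxic T cells, had a median of 1.14 (percentile 100), with 8 of 14 members at least 2-fold higher and 0 lower. The heavy chain genes H2-K1 and H2-T23 were 3.75-fold and 5.41-fold higher at 123 and 16.9 RPKM and the immunoproteasome gene Psmb10 was 4.67-fold higher at 20.7 RPKM, while the light chain gene B2m was at 635 and 505 RPKM. The MHC class II genes of professional antigen-presenting cells had a median of 1.54 (percentile 99.99), with 4 of 5 members at least 2-fold higher, including H2-Ab1, 5.39-fold higher at 42.6 RPKM, and Cd74, the invariant chain, 2.97-fold higher at 102 RPKM. Markers of macrophages, host cells of such tumours, were higher as well, with a median of 0.71 (percentile 100), 8 of 19 members at least 2-fold higher and 2 at least 2-fold lower. The complement genes C1qc and C1qb were 3.42-fold and 2.75-fold higher at 45.5 and 141 RPKM, and Lyz2, the lysozyme of myeloid cells, was at 184 against 105 RPKM. Only 3 of the T and NK cell markers and 1 of the B and plasma cell markers were measured, too few to place, with Cd4 at 1.60 against 0.262 RPKM, Foxp3 at 2.55 against 1.37 RPKM, Cd247 at 0.649 against 2.05 RPKM and the B cell gene Ebf1 at 1.16 against 0.711 RPKM. Cytokine and chemokine genes went both ways, with 3 of 23 members at least 2-fold higher and 6 lower and a median of −0.02 (percentile 71.4). Il18 was 4.96-fold higher at 80.1 RPKM, and Ptgs2, the inducible prostaglandin synthase, was 6.35-fold lower at 2.82 RPKM.

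Genes of mesenchymal transition and those of fibroblasts and matrix were lower in the Brg1-deleted tumour. The RNA is from whole tumours, so tumour cells and host fibroblasts cannot be told apart as the source for either list. Genes of mesenchymal transition had a median of −0.51 (percentile 0.445), with 8 of 21 members at least 2-fold lower and 0 higher. The receptor tyrosine kinase gene Axl was 7.46-fold lower at 4.54 against 33.9 RPKM, Cdh2, which encodes N-cadherin, 6.52-fold lower at 1.82 RPKM, and the fibronectin gene Fn1 4.22-fold lower at 79.7 against 336 RPKM, whereas Vim, the intermediate filament of mesenchymal cells, was at 476 and 375 RPKM. Genes of the matrix and of fibroblasts, another host cell type, had a median of −0.54 (percentile 0.16), with 6 of 23 members at least 2-fold lower and 0 higher. The collagen gene Col6a3 was at 3.15 against 9.45 RPKM, the collagen gene Col5a1 and the proteoglycan gene Lum were 2.66-fold and 2.80-fold lower, and Col1a1 was at 102 and 132 RPKM. Skeletal muscle markers were lower too, with a median of −0.86 (percentile 0.32) and 7 of 17 members at least 2-fold lower, among them the troponin gene Tnnt3 at 6.53 against 20.4 RPKM. Neutrophil genes had a median of −0.93 (percentile 0.2), with 6 of 14 members at least 2-fold lower, led by Lcn2, and 2 at least 2-fold higher. The higher members were the calprotectin subunit gene S100a8, at 15.2 against 3.03 RPKM, and the granule gene Ngp, at 3.50 RPKM and listed at 0 in the other tumour. S100a9, the gene of the other calprotectin subunit, was among the lower members, at 5.40 against 16.1 RPKM. With a pseudocount of 5 RPKM the neutrophil list lay at percentile 3.07, within the central range.

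Adipocyte markers had a median of 0.66 (percentile 99.5) although on the log2(RPKM + 1) scale 0 of 8 members reached 2-fold higher and 1 was at least 2-fold lower, the lipid droplet gene Cidea at 0.848 against 2.97 RPKM. Pparg, the master regulator of fat cell formation, was at 57.2 and 34.1 RPKM, and the fatty acid binding protein gene Fabp4 at 20.04 and 10.6 RPKM. Adipoq, the adiponectin gene, went the other way at 0.748 against 1.54 RPKM. Of the 16 genes on this list 8 were measured, so a change in fat cells cannot be read from it. The endothelial, pericyte and smooth muscle, nerve and Schwann cell, epidermal keratinocyte and erythrocyte lists lay in the central range. Endothelial markers had a median of 0.22 (percentile 94.8) but a mean of −0.08, with Flt4, a receptor of lymphatic vessels, 6.96-fold higher at 5.78 RPKM and Sox17 listed at 0 against 6.86 RPKM. Pericyte and smooth muscle markers had a median of −0.43 (percentile 27.3), nerve and Schwann cell markers −0.49 (percentile 16.5), epidermal keratinocyte markers −0.63 (percentile 16.0) and erythrocyte genes 0.71 (percentile 95.3). The erythrocyte list lay higher without the filter on low values, at percentile 98.2, and against random lists not matched on expression, at percentile 97.7.

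Developmental genes differed in both directions. Hox genes, which set position along the body axis, were higher, with a median log2 ratio of 2.16 (percentile 100) and 10 of 14 members at least 2-fold higher. All measured members except Hoxd8 were below 1 RPKM in the p53 heterozygous tumour, so they entered the list through their values in the Brg1-deleted tumour. Hoxb8 was 23.4-fold higher at 17.8 RPKM, and Hoxa7 was at 7.05 RPKM and listed at 0 in the p53 heterozygous tumour. Oncofetal genes were lower, with a median of −1.09 (percentile 0.28) and 5 of 10 members at least 2-fold lower. Besides Hmga2, the RNA-binding protein gene Igf2bp2 was 17.3-fold lower at 3.80 against 65.6 RPKM and the imprinted RNA H19 4.34-fold lower at 2.16 RPKM. Genes of retinoid metabolism and stellate cells had a median of −0.98 (percentile 0.29), with 4 of 8 members at least 2-fold lower and 1 higher, and the retinol carrier gene Rbp4 and its receptor gene Stra6 were 9.82-fold and 11.2-fold lower, from 111 and 41.8 RPKM. Notch pathway genes had a median of −0.84 (percentile 0.71), with 2 of 8 members at least 2-fold lower on the log2(RPKM + 1) scale, the ligand gene Jag1 at 5.73 against 12.6 RPKM and the receptor gene Notch2 at 4.23 against 10.4 RPKM. The coactivator gene Maml2, at 3.28 against 7.11 RPKM, fell short on that scale, while the Notch target Hes1 was at 18.1 and 21.8 RPKM. The Notch list returned to the central range without the filter on low values and with a minimum of 5 RPKM, at percentiles 18.3 and 2.9, and the retinoid list without the filter, at percentile 16.8.

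The tumours also differed in RNA from the sex chromosomes. Xist, the RNA that coats the inactive X chromosome, was 15.6-fold higher in the Brg1-deleted tumour at 34.6 against 2.23 RPKM. The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d were at 18.2, 5.33, 5.31 and 3.79 RPKM in the p53 heterozygous tumour and at 0, 0.001, 0.001 and 0 RPKM in the Brg1-deleted tumour. The list that joins these 5 genes had a median of −2.66 (percentile 0), a value set by its 4 Y-linked members. Such values go with a difference in sex between the cells of the tumours, from the lines, the hosts or both. The sex of the host mice is not given, and sex cannot be separated from the genotypes here.

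Signalling lists tied to Kras and its partners lay in the central range. KRAS and ERK output genes had a median of −0.32 (percentile 5.27), with 4 of 24 members at least 2-fold lower, including the transcription factor gene Etv4, 3.81-fold lower from 34.3 RPKM, and the phosphatase gene Dusp5, 4.80-fold lower at 1.87 RPKM. With a pseudocount of 5 RPKM this list lay lower, at percentile 1.3. TGF-beta genes had a median of −0.32 (percentile 5.15), with the activin subunit gene Inhba 7.04-fold lower at 1.83 RPKM, the inhibitory Smad gene Smad6 3.52-fold higher at 3.91 RPKM and the matricellular gene Ctgf at 102 and 202 RPKM. Hedgehog pathway genes had a median of −0.55 (percentile 8.20) and Wnt target genes one of 0.05 (percentile 72.7) with a mean of −0.18. The p53 target genes had a median of 0.08 (percentile 90.8), and on the log2(RPKM + 1) scale 1 of 28 members was at least 2-fold higher, Eda2r at 1.48 against 0.187 RPKM, and 1 lower, the death receptor gene Fas at 0.294 against 2.71 RPKM. Gdf15, a stress-induced cytokine gene, was at 1.48 against 0.263 RPKM, just short of 2-fold on that scale. The SWI/SNF subunits had a median of 0.06 (percentile 86.4) and a mean of −0.11, with Smarca2 and Smarca4 as the 2 members past 2-fold on the log2(RPKM + 1) scale, and Smarcd3, 2.22-fold lower at 2.88 RPKM, short of it. Cyclin-dependent kinase inhibitors had a median of −0.11 (percentile 53.03) but a mean of −1.02. Of the 7 measured members 2 were at least 2-fold lower, Cdkn2a and Cdkn2b, and 0 higher, while Cdkn1b was at 32.9 and 35.5 RPKM. Polycomb and chromatin regulators had a median of −0.22 (percentile 25.2), with the histone methyltransferase gene Ezh2 3.02-fold lower at 7.90 RPKM and Uhrf1, which recruits maintenance DNA methylation, 2.21-fold higher from 6.79 RPKM.

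Among growth and metabolic lists the shifts of the medians were small, although single members differed more. Mitosis genes had a median of 0.25 (percentile 99.0), with 1 of 25 members at least 2-fold higher, the kinase gene Cdk1 at 11.96 against 5.17 RPKM, and Mki67, a marker of cycling cells, at 43.5 and 37.6 RPKM. DNA replication genes had a median of 0.16 (percentile 97.0) and replication-dependent histone genes one of −0.30 (percentile 39.0). Oxidative phosphorylation genes had a median of 0.22 (percentile 98.8), with 3 of 31 members at least 2-fold higher, including the complex I gene Ndufa1 at 78.1 against 31.6 RPKM, and 1 lower, Ndufs3 at 2.97 against 15.4 RPKM. Unfolded protein response genes had a median of 0.28 (percentile 98.2), with 1 of 18 members at least 2-fold higher on the log2(RPKM + 1) scale, the asparagine synthetase gene Asns at 38.6 against 18.5 RPKM. The stress-induced transcription factor gene Atf3 was at 4.33 against 1.89 RPKM and Trib3 at 1.60 against 3.50 RPKM, both short of 2-fold on that scale. Hypoxia and glycolysis genes had a median of −0.14 (percentile 27.6), with 2 of 26 members at least 2-fold higher and 7 lower. Car9, a carbonic anhydrase induced by hypoxia, was 11.3-fold higher at 117 RPKM, and the lactate exporter gene Slc16a3 was 12.1-fold lower at 1.87 RPKM. Detoxification genes had a median of 0.18 (percentile 95.3), with the glutathione transferase genes Gsta3 and Gsta4 6.31-fold and 2.24-fold higher at 77.6 and 672 RPKM. Cholesterol synthesis genes had a median of −0.17 (percentile 36.2), immediate early genes 0.08 (percentile 84.1) and cytosolic ribosomal protein genes 0.08 (percentile 85.4). Most measured members of the ribosomal list have a near-identical copy, so its median is uncertain.

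**Figure D3:**
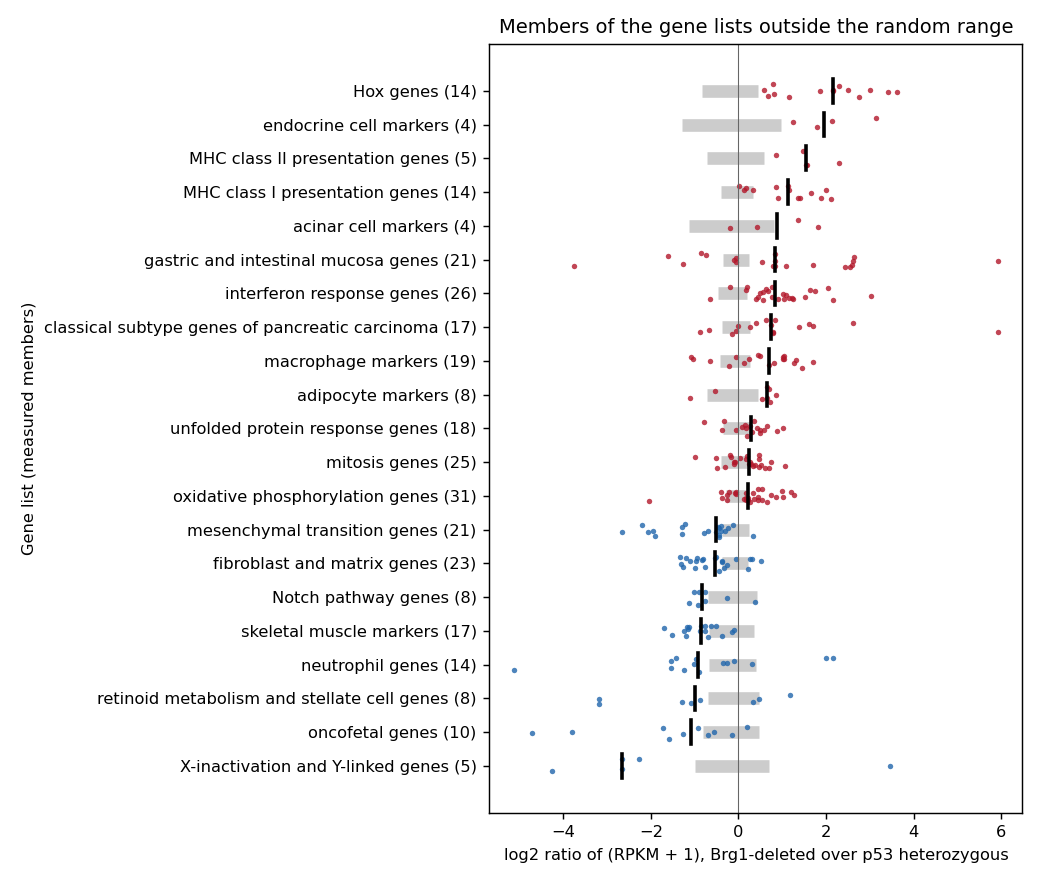
log2 ratios of (RPKM + 1), Brg1-deleted over p53 heterozygous tumour, of the measured members (points) of the 13 gene lists that lay higher (red) and the 8 that lay lower (blue) than random lists, with the number of members in brackets. Black bars are medians and grey bars the central 95% of 10000 random lists of the same size and expression; the medians run from 2.16 for Hox genes to −2.66 for the X-inactivation and Y-linked genes.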

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

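The alternatives without near-identical copies, without names that match no current symbol and without genes listed at 0 were chosen after seeing the data, and the last leaves too few members to place the acinar, endocrine, histone and X and Y lists. No paired analysis was possible because each group had 1 library, and for the same reason no library could be left out. The counts of 159 higher and 340 lower genes became 561 and 981 with a pseudocount of 0.1, 37 and 59 with a pseudocount of 5, 523 and 873 after rescaling to equal sums, which makes the pseudocount smaller relative to the values, and 1086 and 1694 at a threshold of 1. They were 190 and 297 after centring, 125 and 275 with a minimum of 5 RPKM, 147 and 334 without copies, 139 and 298 without unmatched names and 116 and 233 without genes at 0. The higher genes made up 31.9% of those called, and 39.0% after centring. Of the lists, the acinar markers left the higher range with medians of 1.22 (pseudocount 0.1), 0.32 (pseudocount 5), 1.24 (rescaled) and 0 (no filter), the endocrine markers with 0 (no filter), and the neutrophil genes left the lower range with −0.28 (pseudocount 5), the Notch genes with −0.28 (no filter) and −0.85 (minimum of 5 RPKM) and the retinoid genes with −0.089 (no filter). Dropping the filter by its construction adds members below 1 RPKM in both libraries; the cause of the other shifts was not tested. The number of lists called higher ran from 11 to 15 and of those called lower from 6 to 8 over the alternatives, and 433 list values kept their call, 9 lost it and 5 gained one. Of the values for named genes 675 stayed on their side of the 4-fold rule, 37 fell short of it, 33 of these with a pseudocount of 5, and 40 passed it newly. No list or named gene past its threshold turned in direction under these alternatives. The depth is unknown, so which values it limits was not measured.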

Other observations

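The genes and gene families in this part, and the tests of scaling, of chromosome segments, of macrophages, of the neighbours of the MHC genes and of near-identical copies, were chosen after the results were seen. The search for copies and the bounds of its tests were also revised after first results had been seen, and under the first revised bounds the test of large ratios had counted against shared reads. The bounds of the remaining tests, the regression on GC content, length and expression and the MHC class I genes outside chromosome 17, were written before those results were seen.

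Some single genes outside the lists had large ratios and are given as values, with no statement on the groups they belong to. The calcium-activated channel regulator gene Clca3 of goblet cells was 11.1-fold higher at 58.4 against 5.28 RPKM, the mucin gene Muc3 16.8-fold higher at 12.96 RPKM, the antimicrobial lectin gene Reg3b 10.3-fold higher at 75.9 RPKM and Spink4, a secreted inhibitor of goblet cells, 7.46-fold higher at 61.6 RPKM. Nkx2-3, a homeobox gene of the gut and spleen, was 8.04-fold higher at 18.9 RPKM, and Penk, which encodes proenkephalin, 8.70-fold higher at 81.7 RPKM. In the other direction, the developmental transcription factor genes Pax2 and En1 were listed at 0 against 12.4 RPKM and at 0.601 against 23.3 RPKM, and the aggrecan gene Acan was at 0.175 against 22.7 RPKM. The complement gene C3 was 18.9-fold lower at 5.91 against 112 RPKM, and Gc, the vitamin D binding protein, was at 1.02 against 35.7 RPKM.

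Among 194 gene families formed by name with at least 8 measured members, 20 lay outside the central 95% of random lists. By chance 9.7 are expected if members vary independently. Members of a family can vary together, so this count does not show an excess over chance. Claudin genes, which seal epithelial junctions, were lower with a median log2 ratio of −1.66 (5 of 9 members at least 2-fold lower), as were the Ugt genes of glucuronidation with −1.03 (10 of 13), many of which share exons and so reads. Box C/D small nucleolar RNA genes had a median of −1.96, with 14 of 20 members at least 2-fold lower and 4 higher. The other families of short RNAs were lower as well. Genes named Snora had a median of −1.36 (8 of 13 lower, 2 higher) and genes named Mir one of −0.98 (19 of 39 lower, 5 higher). A technical difference between the libraries in short RNAs was not tested. The protocadherin alpha genes had a median of 1.35, with 12 of 13 members at least 2-fold higher, while the protocadherin gamma-A genes had one of −0.81 (percentile 0.12), with 0 of 12 members past 2-fold in either direction. The members of each of these families share exons too. Mitochondrial ribosomal protein genes of the large subunit had a median of 0.25, with 5 of 46 members at least 2-fold higher and 0 lower, and galectin genes one of 0.79, with 3 of 9 members at least 2-fold higher.

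Genes on chromosomes 18, 3 and 8 were lower as a whole, with median log2 ratios of −0.55 (342 genes), −0.52 (630 genes) and −0.43 (688 genes), and those on chromosome 4 were higher with 0.26 (746 genes), and these 4 of the 20 chromosomes were singled out because their medians lay furthest from that of all genes, followed by chromosomes 10 with 0.17 and 5 with −0.36. A difference in scaling moves all chromosomes alike, whereas the highest and lowest medians differed by 0.81, and after regression on GC content, transcript length and expression level 4 of 4 medians still lay outside the central 95% of random sets, as did 8 of the other 16. When each of these chromosomes was divided into 8 segments, 32 of 32 segments lay on the chromosome's own side of the median gene, but all 8 segments also lay on one side for 5 of the other 16 chromosomes, so neither result is particular to the 4. Gain or loss of whole chromosomes in one of the tumours may underlie these shifts, as a hypothesis, but copy number was not measured and the data do not show in which tumour it would lie. Smad4, a tumour suppressor gene of pancreatic cancer on chromosome 18, was at 19.7 against 34.4 RPKM.

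Interferon response and MHC class I genes were higher in the Brg1-deleted tumour, and so were macrophage markers. The 26 measured interferon genes all lie outside chromosome 17, so explanations from the MHC region were weighed for the MHC class I genes, and a gain of that region is argued against by its 71 neighbours of other gene groups, which the MHC class I genes on chromosome 17 exceeded by 1.245 on the log2 scale (95% bootstrap interval over genes 0.95 to 1.71). More macrophages could be neither shown nor excluded as the source of either list. The medians exceeded that of the macrophage markers by 0.13 (−0.38 to 0.83) for interferon genes and 0.43 (−0.36 to 1.20) for MHC class I genes. Both intervals run from below the macrophage median to above it, so tumour and host sources cannot be told apart. For the MHC class I genes strain variants against the reference stay open too, and the labels give a mixed background. The 6 members outside chromosome 17 had a median of 0.25 (percentile 84.8) against 1.39 for the 8 members on it. That median lay within the central 95% of random sets, which met the bound written beforehand for strain variants. The question was left open after the result was seen, because the members outside chromosome 17 differed widely. Psmb10 was at 20.7 against 4.42 RPKM in the p53 heterozygous tumour and Erap1 at 10.9 against 5.6 RPKM. B2m, Canx, Pdia3 and Calr had log2 ratios of 0.33, 0.18, 0.14 and 0.015. A difference between the genotypes is another open explanation, untested because each has 1 library.

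Several genes that every cell uses had large ratios or values near 0, such as Gapdh at 0.368 and 0.331 RPKM, Ppia, for which the search found no near-identical copy, at 0.252 and 0.364 RPKM and Kpna2 at 11.2 RPKM and listed at 0, beside the control gene Actb at 451 and 468 RPKM. Reads shared with pseudogenes and paralogs may be the cause for genes with a copy, but the tests left this open. Among 799 measured genes with a near-identical copy 2.25% passed the 4-fold rule, at percentile 2.11 of matched genes without one. Copies thus did not go with more large ratios among measured genes, although 4 of the 24 named genes with the most extreme ratios had a copy where 1.55 were expected. Genes below 1 RPKM in both libraries, such as Gapdh, were outside this test. Reads lost alike in both libraries would also leave a ratio unchanged, so the test cannot decide the question. For values near 0, the 62 ribosomal protein genes with a copy had a median of 5.40 RPKM in the higher library and the 17 without 17.98 RPKM, a difference at percentile 14.2 of random reassignments. The treatment of such reads is not given in the sources used here, so for these genes shared reads and other sources cannot be told apart, and no biological explanation was tested.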
